A study of Mus musculus with 8 samples.

How the data were processed

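Pumilio proteins are RNA-binding proteins that recognise short sequence elements in mRNA. Crosslink sites of Pum1 and Pum2 were measured by iCLIP (individual-nucleotide resolution crosslinking and immunoprecipitation) in neonatal mouse brain. Per the labels, 0.5 g of tissue was crosslinked with ultraviolet light of 254 nm, RNA was trimmed with RNase 1, and complexes were recovered with antibodies against Pum1 or Pum2. There were 8 libraries in 4 groups of 2: wild-type (WT) brain with Pum1 iCLIP, WT brain with Pum2 iCLIP, Pum1 knockout brain with Pum1 iCLIP, and Pum2 knockout brain with Pum2 iCLIP. The number of PCR cycles differed between samples per the labels, and each group had its own barcode.

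The authors deposited 1 list of called sites per library, on genome build mm10. Each deposited list gives, per site, the position, the strand and a height, which is a whole number (counts) from 2 up. In a text field the deposited lists also give other values: a cluster name, the height again, a background height and a P of at most 0.001. The aligner, the peak caller, the collapsing of reads, the total read counts and any filtering of the lists by gene, chromosome or knockout before deposit are not given in the sources used here. The Pum1 knockout list of replicate 2 was a single empty line. Whether no site was called or the list is incomplete is not known, and it was counted as 0 sites and left out of shares. Identical repeated lines were counted once, which removed 690 and 1792 lines from the WT Pum1 lists and 580 and 664 from the WT Pum2 lists. Heights ranked sites within a list and were never compared between lists. A planned count test of signal per gene was not run, since heights exist at called sites alone.

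Sites and genes were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The annotation was GENCODE mouse release M21, with 55536 genes, of which 22028 were protein-coding. A site was assigned by its midpoint on its own strand, in the order 3' UTR, CDS, 5' UTR, noncoding exon, intron, antisense, outside genes. Sequence was taken from annotated transcripts, so the motif was searched at sense exonic sites, and sequence in introns, antisense to genes and outside genes was not analysed here. The motif was the Pumilio element UGUANAUA, where N is any base, within 20 nt of the site midpoint. Each site had 1 matched window, placed at random in the same part of the same transcript.

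Numbers of sites and shares per library were compared between 4 WT and 4 knockout libraries (3 where shares were needed) by exact two-sided permutation tests over every split. Replicate overlap (1 nt or more, same strand) was compared, one-sided, with 100 random placements of the same sites in the gene parts that held them. Motif shares were compared by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 17 tests. Words of 6 nt were tested in the same way over all 4096. A reproducible region was the merged overlap of a replicate 1 and a replicate 2 site, and it was dropped when a knockout site of the same protein overlapped it. Target genes were genes with a region left, read against the 7414 genes with a sense site in any library. Targets were tested against 20 gene lists by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 40 tests. Intervals are exact (Clopper-Pearson) 95% binomial intervals, except for odds ratios in the closing part, where they are Woolf intervals. They cover counting error over sites alone, and neighbouring sites are not independent.

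The comparisons, the 20 gene lists, the rule for naming genes and most alternative settings were chosen before the data were examined. The rule named Pum1, Pum2 and Norad always. It then named the 20 targets per protein with the highest score, where the score is the lower of the replicates' percentile ranks of the gene's highest site. It also took 5 genes with the highest sense site per knockout list, up to 4 members per gene list, up to 10 targets per protein without a site of the other protein, and up to 10 genes with a shared 3' UTR region that held the motif. Genes with the most sites per library were named after the data were seen. Repeated lines were not foreseen, so counting them once and the setting that kept them were both chosen after the files were read. Sense sites within genes, the list without the empty library, the exon-only settings, gene length matching and the removal of sites of equal height were chosen after the data were seen.

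The steps were tested on simulated data. When 10% of the Pum1 replicate 1 sites were copied into the other list, 10.2% were found, and for Pum2 10.0% were found. A motif written into 5% of windows raised the share by 5.00 points for both proteins. At the size of the Pum1 regions (437 windows) the 3 words of the element were found when 10% of windows held it. At the size of the Pum2 regions (197 windows) 0 of 3 were found at 10%, and 3 at 20%. Random gene sets gave 3 calls in 4000 list tests.

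Alternatives changed 1 choice at a time, except that exons alone changed both the targets and the gene background (4764 genes with an exonic site). They covered the overlap that counts as shared, the upper 50% of each list by height, lists of equal length, strand, mitochondrial sites, the knockout filter, motif and window size, control windows, the gene background, matching on 3' UTR or gene length with 10000 random sets, leaving out each replicate, and comparison within replicate numbers.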

Results

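Sites were listed for 7 of the 8 libraries from neonatal mouse brain, with 2 biological replicates in each of 4 groups. The knockout libraries served as negative controls for the antibody against the missing protein. WT Pum1 iCLIP gave 6978 sites in replicate 1 and 15121 in replicate 2, and WT Pum2 iCLIP gave 9874 and 12447. The Pum1 knockout list held 994 sites in replicate 1 and 0 in replicate 2, an empty list that may be incomplete, and the Pum2 knockout lists held 1851 and 7426. Heights summed to 99386 and 140800 in the WT Pum1 lists and to 129355 and 142054 in the WT Pum2 lists. They summed to 12599 in the Pum1 knockout list with sites, and to 18724 and 73254 in the Pum2 knockout lists. The median height per site lay between 6 and 8 in every list with sites. Positions are on mm10, counted from 1.

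The first comparison asked how much signal each antibody gave where its protein was missing, starting with the targeted genes themselves. RNA of Pum1 (chromosome 4) carried 22 and 20 sites in the WT Pum1 replicates and 0 in the Pum1 knockout list with sites. RNA of Pum2 (chromosome 12) carried 12 and 8 sites in the WT Pum2 replicates, and 0 and 1 in the Pum2 knockout. Whether a knockout also lost the RNA of its deleted gene was not tested. Such a loss would give the same counts, so they do not measure background. In WT brain each antibody also gave sites on the other protein's RNA: Pum2 RNA held 38 and 33 WT Pum1 sites, and Pum1 RNA held 16 and 6 WT Pum2 sites. The long noncoding RNA Norad (2900097C17Rik, chromosome 2), known for its many Pumilio elements, had 38 and 28 sites with Pum1 and 26 and 21 with Pum2. Norad had 30 sites in the Pum1 knockout list, and 1 and 2 in the Pum2 knockout lists. Pum2 RNA likewise had 23 sites in the Pum1 knockout list. The WT Pum1 sites on Norad and on Pum2 RNA thus do not by themselves mark crosslinks of Pum1.

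Counting every listed site, within genes or not, WT Pum1 lists averaged 11049.5 ± 5758 sites (SD, n = 2) and WT Pum2 lists 11160.5 ± 1819 (SD, n = 2). The Pum1 knockout averaged 497 ± 703 and the Pum2 knockout 4638.5 ± 3942 (SD, n = 2 each). Beyond Norad and Pum2, the Pum1 knockout sites were densest in Slc38a2 (16 sites), a neutral amino acid transporter, in Atp2a2 (15), a calcium pump, and in the ubiquitin ligase March6 (15). In replicate 1 of the Pum2 knockout, the motor protein gene Kif5a led with 14 sites. In replicate 2 the transcription factor gene Pbx1 had 41, Phactr1 27, Nrg1 27, and the splicing factor gene Rbfox1 26. Among sense sites within genes, the highest of the knockouts lay elsewhere. In the Pum1 knockout they were intronic, in 4930558K02Rik (height 326), Prkag2 (229), Gm49497 (227), AC140233.1 (227) and 4930402H24Rik (170). In Pum2 knockout replicate 1 they were in Gm44511 (96), the Y RNA Rny3 (44), Gpc5 (39), Kng1 (39) and Gjc1 (38), below a maximum of 197 over the whole list. In replicate 2 they were in Zdhhc9 (431), Usp17la (424), Rny3 (327), Gm44511 (313) and the translation factor gene Eif4g2 (224), below a list maximum of 1457. The mean of log10(sites + 1) was 4.03 in 4 WT and 2.53 in 4 knockout libraries, a difference of 1.49 (exact two-sided permutation p = 0.0571 over 70 splits, where 0.0286 was the smallest possible). Repeated lines were counted once there, a choice made after the files were read, and with repeats kept the difference was 1.53 (exact p = 0.0286). With settings added later it was 0.650 without the empty list (exact p = 0.114) and 1.62 in sense sites within genes (exact p = 0.0286).

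**Figure D1:**
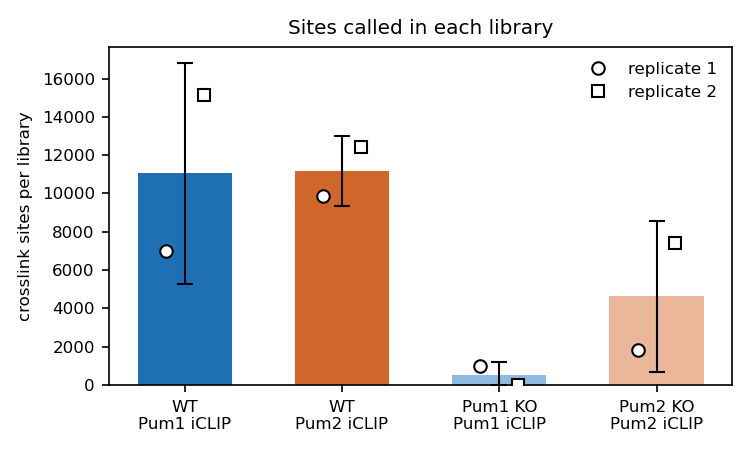
Crosslink sites per library (vertical axis, number of sites) for the 4 groups, with bars for means, lines for 1 SD (cut at 0) and points for the 2 replicates. The WT libraries lie between 6978 and 15121 sites and the knockout libraries between 0 and 7426, so the ranges overlap.

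WT Pum1 sites lay mostly in 3' UTRs and WT Pum2 sites mostly in introns. In WT Pum1 lists 61.9% ± 2.62 of sites (SD, n = 2) were in 3' UTRs, 17.6% ± 5.20 in CDS and 10.9% ± 0.205 in introns. In WT Pum2 lists 16.6% ± 5.31 (SD, n = 2) were in 3' UTRs, 2.75% ± 0.851 in CDS and 61.5% ± 11.0 in introns. With Pum1, replicate 1 had 44 sites in Qk, an RNA-binding protein gene, of which 43 were in the 3' UTR. It had 40 in the myelin proteolipid relative Gpm6b and 33 in the kinase gene Gsk3b, and in Tsnax all 46 sites were intronic. Replicate 2 of Pum1 had 37 sites in the sodium channel gene Scn2a, 36 in Nrxn1 and 33 in the Wnt pathway gene Apc. With Pum2, Ulk4 had 124 sites in replicate 2, Rbfox1 had 37 and 60 sites, Auts2 28 and 57, and Pbx1 39 and 52.

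In the Pum1 knockout 46.3% of 994 sites (95% exact interval 43.1 to 49.4) were in 3' UTRs and 11.9% in introns. In the Pum2 knockout 4.76% ± 3.06 (SD, n = 2) were in 3' UTRs and 44.6% ± 10.0 in introns. Over 4 WT and 3 knockout libraries the mean 3' UTR shares, 39.2% and 18.6%, did not separate (exact permutation p = 0.286 over 35 splits, smallest possible 0.0571). The WT mean held 2 lists per protein, and the knockout mean 1 Pum1 and 2 Pum2 lists. The gap of 20.6 points thus also reflects the mix of proteins. Within 3 pairs of protein and replicate number it was 13.7 points. The picture depended on the sites counted. Among sense sites within genes, the 3' UTR share of the Pum1 knockout was 64.1%, between 63.3% and 70.4% in the WT Pum1 lists. Introns then held 86.3% ± 7.30 in the Pum2 knockout and 73.9% ± 7.11 in WT Pum2 lists (SD, n = 2 each), where over all sites the WT share was the higher. The gap between WT Pum1 and WT Pum2, 45.3 points in 3' UTRs and -50.6 in introns, exceeded the spread between replicates, though 2 against 2 libraries give an exact permutation p of 0.333 at the smallest. The knockout lists differed in the same direction. Among sense sites within genes, 3' UTRs held 64.1% in the Pum1 knockout and 8.59% on average in the Pum2 knockout, and introns 16.4% and 86.3%. The WT gap thus does not by itself mark a difference in binding between the proteins. Sites outside genes made up 1.08% of WT lists on average and 31.7% of knockout lists. The sources do not say whether WT lists were restricted to genes before deposit, so this contrast and the shares over all sites cannot be read as a difference in binding.

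**Figure D2:**
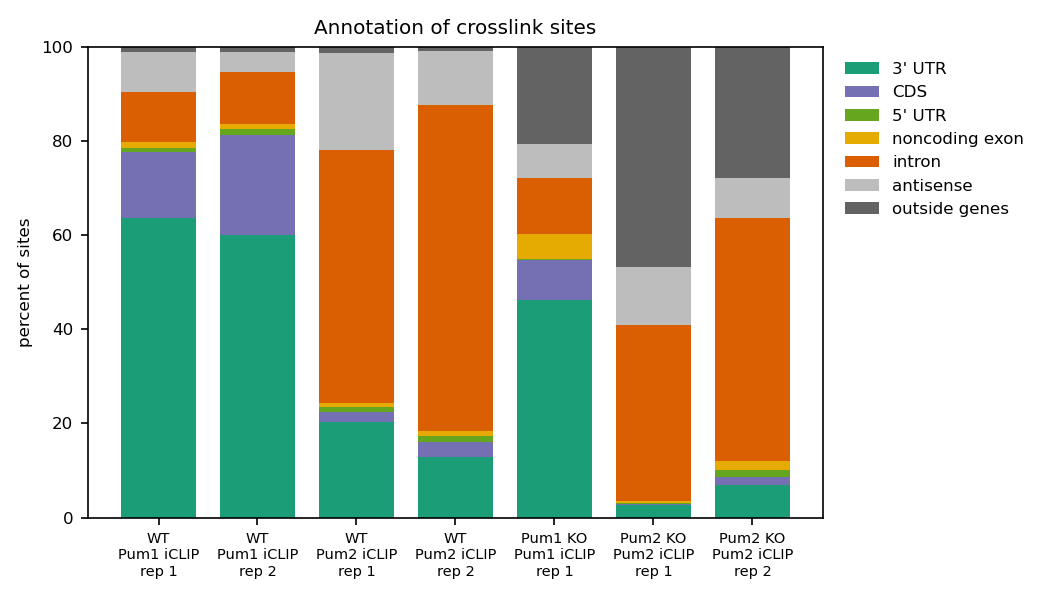
Share of sites (vertical axis, percent) in each gene part, by library, for the 7 libraries with sites. The 3' UTR share averaged 61.9% in WT Pum1 and 16.6% in WT Pum2 libraries, and the share outside genes was near 1.08% in WT and 31.7% in knockout libraries; whether WT lists were restricted to genes before deposit is not known.

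Replicates of a protein shared far more sites than random placement gave. Of the Pum1 sites of replicate 1, 8.31% overlapped a replicate 2 site, and of those of replicate 2, 3.84% overlapped one of replicate 1. The mean, 6.07%, was 41.5 times the 0.146% of random placements. For Pum2 the shares were 9.16% and 7.26%, and their mean of 8.21% was 309 times the random 0.0266%. Each passed all 100 placements (one-sided permutation p = 0.0099, the smallest they can give). Within 50 nt the shares rose to 28.5% for Pum1, with 12.5% at random, and to 30.6% for Pum2, with 2.19% at random. Lists without the protein overlapped WT lists of the other number as well. Of the Pum1 knockout sites, 7.34% overlapped a WT Pum1 replicate 2 site, and 40.5% lay within 50 nt of one. For the Pum2 knockout lists, overlap with the other-numbered WT Pum2 list was 2.32% and 3.27%, and 23.2% and 19.3% within 50 nt. The excess over random placement thus does not by itself mark binding by the protein.

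Few WT positions were also called in the matching knockouts. Pooled over replicates, 0.344% of 22099 Pum1 sites (95% exact interval 0.271 to 0.430) and 1.35% of 22321 Pum2 sites (1.21 to 1.51) overlapped a knockout site of the same protein. Within 50 nt these shares were 3.64% and 17.8%. Such shares are bounded by the length of the knockout lists, and the Pum1 knockout list held 994 sites. Seen from that list, 7.34% of sites overlapped one of WT Pum1 replicate 2, and 0.302% one of replicate 1. The exact overlap depended on the replicate number. WT and knockout lists of the same number shared 3 Pum1 sites, and 5 and 11 Pum2 sites, while lists of different number shared 73 for Pum1, and 243 and 43 for Pum2. At distances of up to 2 nt the lists of the same number had 66, 78 and 359 sites. Exact overlap with the knockout of the same number was thus nearly missing from the WT lists as deposited, and it does not measure background there.

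The next comparison asked whether crosslinks lay at the element that Pumilio proteins recognise. The element UGUANAUA stood within 20 nt of 7.17% of exonic sites in WT Pum1 replicate 1 (95% exact interval 6.51 to 7.88) and 3.72% in replicate 2 (3.40 to 4.07). In WT Pum2 it stood at 13.2% (11.9 to 14.6) and 4.30% (3.51 to 5.21). Matched windows in the same transcripts held it in 1.39% to 1.90%. Sites in 3' UTRs had it at 8.25% and 4.86% with Pum1 and 14.6% and 5.58% with Pum2, while CDS sites had it at 2.47% and 0.652% with Pum1 and 6.13% and 1.20% with Pum2. In the Pum1 knockout the share was 3.50% (2.18 to 5.30) beside 3.33% in 1 draw of matched windows and 2.33% on average over 100 draws (1% to 4%), and in the Pum2 knockout it was 1 of 65 windows and 3 of 894.

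Pooled WT sites had the element more often than matched windows, with an odds ratio of 3.02 for Pum1 (18224 windows, exact adjusted p = 3.97e-66) and 5.91 for Pum2 (4703 windows, exact adjusted p = 1.14e-59), and the share was higher in 4 of 4 WT libraries. Reproducible regions gave 12.6% against 2.97% for Pum1 (odds ratio 4.70, exact adjusted p = 1.76e-07) and 10.2% against 2.03% for Pum2 (odds ratio 5.45, exact adjusted p = 0.00188). Against the knockout, the odds ratio was 23.2 for Pum2 (exact adjusted p = 9.71e-29) and 1.38 for Pum1 (exact p = 0.171, adjusted p = 0.223), so no difference was detectable for Pum1 pooled over replicates. The Pum1 odds ratio was 2.13 without WT replicate 2 (exact p = 3.23e-04) and 1.07 without WT replicate 1 (exact p = 0.912). In 3' UTR sites alone it was 1.66 (exact p = 0.0434, adjusted p = 0.0671). With WT reproducible regions set against all knockout sites it was 3.97 (exact p = 4.60e-08). Only the WT side was selected for recurrence there, so that value mixes selection with genotype. The Pum1 odds ratio turned to 0.833 with the shorter element UGUA (exact p = 0.0394) and to 0.749 within 100 nt (exact p = 0.00894). For Pum2 it was 10.7 without WT replicate 1 (exact p = 3.38e-11), 36.3 without WT replicate 2 and 6.21 without knockout replicate 2 (exact p = 0.0422, not adjusted). Library by library, the mean share was 7.10% in 4 WT and 1.79% in 3 knockout libraries (exact permutation p = 0.0571, the smallest possible). The knockout mean again held 1 Pum1 and 2 Pum2 lists, so it does not weigh the proteins equally. The libraries no longer separated fully with UGUAHAUW (exact p = 0.114), or with UGUA, UGUANAU, 50 nt or 100 nt (exact p = 0.171 each).

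**Figure D3:**
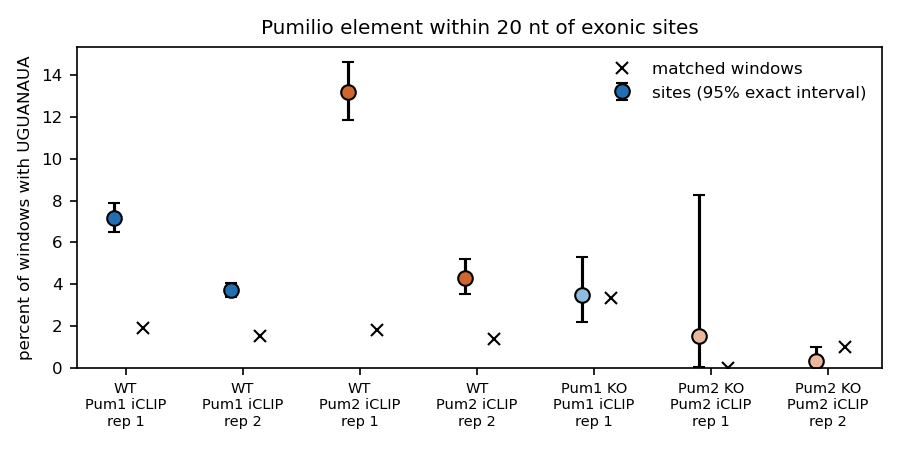
Share of exonic site windows with UGUANAUA within 20 nt (vertical axis, percent) by library, with 95% exact intervals, beside matched windows. The 4 WT libraries lie between 3.72% and 13.2%, and the Pum1 knockout lies at 3.50%, next to 1 draw of its matched windows at 3.33%.

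The element was more frequent just downstream of the crosslink than farther away in WT lists. Its start was 1 to 3 nt downstream of the site in 2.57% (95% exact interval 2.17 to 3.02) and 0.987% (0.823 to 1.18) of exonic WT Pum1 sites, and in 7.33% (6.32 to 8.45) and 1.56% (1.10 to 2.16) of exonic WT Pum2 sites. These were 12.6, 7.48, 43.0 and 12.5 times the share at an equal span of positions from 31 to 100 nt away. The commonest distance was 1 nt in both WT Pum1 lists, and 1 and 2 nt in the WT Pum2 lists. In the Pum1 knockout 2 of 600 exonic sites (0.333%, interval 0.0404 to 1.20) had the element there, 1.48 times the far positions. In the Pum2 knockout it was 0 of 65, which allows up to 5.52%, and 1 of 894.

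**Figure D4:**
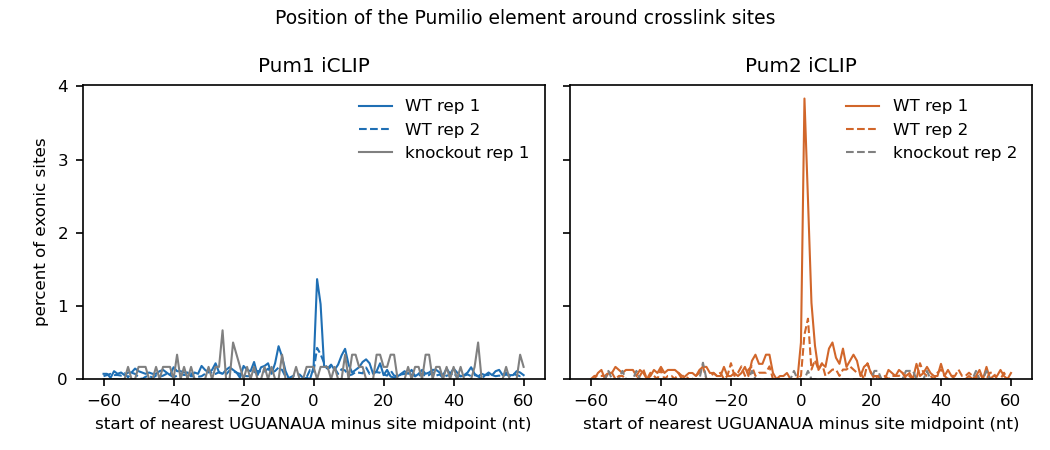
Share of exonic sites (vertical axis, percent) whose nearest UGUANAUA starts at each distance from the site midpoint (horizontal axis, nt), for Pum1 and Pum2 iCLIP. The Pum2 knockout library of replicate 1, with 65 exonic sites, is not drawn; the WT lines peak 1 to 2 nt downstream of the site.

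Words of 6 nt in reproducible exonic regions held the core of the same element. TGTAAA ranked first for both proteins, in 14.6% of 437 Pum1 windows against 3.66% of matched windows (exact adjusted p = 5.71e-05) and in 12.2% of 197 Pum2 windows against 0.508% (exact adjusted p = 0.00319). For Pum1, 16 words were enriched, 6 of them with TGTA, and the others among the first 10 were mostly runs of T such as TTTTTG (8.24% against 1.83%). For Pum2, 3 words were enriched, and CCTCCC (14.7% against 2.54%) and CCCTCC (17.3% against 4.06%) followed TGTAAA. No word was depleted for either protein. With control windows 200 nt downstream, 2 words were past the threshold for each protein, and the counts rose to between 258 and 300 for Pum1 and between 103 and 174 for Pum2 when sites of 1 replicate took the place of regions.

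Pum1 had 374 target genes, through 578 reproducible regions, of which 65.9% were in 3' UTRs. In 287 of the genes a region lay in the 3' UTR, and 59 had intronic regions alone. Among the 20 genes with the highest scores, those with their highest region in the 3' UTR were Ptma, coding for prothymosin alpha (chromosome 1, position 86530413, heights 82 and 60), Marcks, a kinase substrate of growing axons (chromosome 10, 37134866, heights 83 and 41), and Arl8a, a lysosomal GTPase (chromosome 1, 135156222, heights 85 and 40). Norad had its highest region at 156391166 of chromosome 2, with heights 86 and 37. Ndufs7, a complex I subunit, had its region in the 5' UTR (chromosome 10, 80249185, heights 241 and 281), and Washc1 had it in the CDS (chromosome 17, 66119070, heights 509 and 233). The other 14 genes had it in an intron: Gm42788, Vmn2r97, Adarb2, Etl4, Zfp791, Ntm, Rap1gap2, 4930578N18Rik, Pik3c2a, Snx6, Dach1, Acer3, Elf1 and Ipo8. In the first 4 of these the replicate 1 heights were nearly equal, at 998, 987, 995 and 1003, with 1 Pum1 site per list in each gene. The knockout filter removed 2 of 580 regions for Pum1, and 5 of 904 for Pum2. It could remove few, since exact overlap with the same-numbered knockout was nearly missing from the WT lists as deposited. So it says little about background in these targets. When a knockout site anywhere in the gene excluded it, 248 Pum1 targets were left, and with overlap within 50 nt there were 1107.

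Pum2 had 563 target genes, through 899 reproducible regions, of which 58.4% were in introns and 18.8% in 3' UTRs. In 139 of the genes a region lay in the 3' UTR, and 404 had intronic regions alone. The highest score belonged to Peg10, an imprinted gene derived from a retrotransposon, in its 3' UTR (chromosome 6, 4760390, heights 120 and 170). The 3' UTRs of Ttc39b (chromosome 4, 83223725, heights 81 and 61), St8sia1, a ganglioside synthase (chromosome 6, 142822079, heights 173 and 37), the cell adhesion gene Chl1 (chromosome 6, 103732988, heights 38 and 34), Ptms, Nemp1 and Cd24a were also among the 20. Prpf3, a splicing factor gene, had its highest region in the 5' UTR. The other 12 had it in introns: Lrp1b, Kif5a, Slc23a2, 6530403H02Rik, Cmss1, Hs3st4, Cdh23, Pbx1, Spata5, Ntm, Zfp791 and Fam19a5. Of these 20 genes, 17 also had sites in a Pum2 knockout list, such as Kif5a with 14 and 10 and Peg10 with 0 and 5. Of the 20 Pum1 genes, 7 had sites in the Pum1 knockout list. The Pum1 knockout list was shorter, and over all targets 248 of 374 Pum1 genes and 194 of 563 Pum2 genes had no knockout site, so these counts do not compare the proteins. With knockout sites excluding whole genes 194 Pum2 targets were left, with regions in exons alone 159, and with overlap within 50 nt 1113.

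The targets of both proteins were compared to see how far they were shared. Of the targets, 101 genes were shared, 3.56 times the 28.4 of chance among 7414 genes (Fisher's exact p = 4.84e-32). With regions in exons 68 genes were shared, 6.47 times chance among the 4764 genes with an exonic site (exact p = 2.63e-40), and with regions in introns 22, 4.0 times chance among 4492 (exact p = 4.58e-09). These backgrounds differ, so the folds are not comparable with each other. At the level of positions, 67 regions in 47 genes were the same for both proteins, which is 11.6% of Pum1 regions and 7.45% of Pum2 regions, and 30 of them were in 3' UTRs. In 9 genes such a shared 3' UTR region held the element. It was TGTAAATA in Adgrl1 and Sdc3, where it started 9 nt upstream of the site (-9), in Serinc1 and Vgf (2 nt downstream), in Taok1 (6 nt), in Pcdh11x (1 nt) and in Zfp12 (7 nt). It was TGTACATA in Rpl19 and Nptxr, 1 nt downstream. Adgrl1 is a latrophilin at synapses, Vgf a neuropeptide precursor and Nptxr a pentraxin receptor. When replicate 2 sites stood in for regions the fold was 0.931 (exact p = 3.92e-11), and with replicate 1 sites it was 1.21. The replicate 2 sets held 4173 Pum1 and 3614 Pum2 genes, and the 7414 background genes were drawn from these same lists. That limits how high the fold can go, so these folds are not comparable with 3.56. How much of the fall this explains was not tested. The main fold depends on the background too, at 10.9 over all protein-coding genes.

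Some targets had no site of the other protein. Of the Pum1 targets, 46 (12.3%) had no WT Pum2 site, led by Gsk3a, a paralogue of Gsk3b (4 and 8 Pum1 sites), BC030870, Polr2m, the amino acid transporter gene Slc7a1 (3 and 6), Ldha (1 and 3), Cnbp (1 and 7), Rnf44, Ckb, Fbxo21 and Tmem258. Cnbp held the element in its highest region. Of the Pum2 targets, 180 (32.0%) had no WT Pum1 site, led by Ttc39b (6 and 8 Pum2 sites), 6530403H02Rik (4 and 2), Hs3st4 (9 and 27), Prpf3, Rgs9, Kynu, 9230009I02Rik, Cep128, Ccdc97 and Glis3. Hs3st4 had 5 and 14 sites in the Pum2 knockout. The highest regions of the named Pum1 targets were in 3' UTRs, except for BC030870, with an intronic one.

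Gene lists were tested to see which kinds of brain genes the targets held. Among Pum1 targets the known Pumilio targets stood out, with 9 of 27 members that had a site in any library (odds ratio 9.62, exact adjusted p = 5.34e-05), among them Norad, the antiproliferative gene Btg1, Pum1 and Pum2. Neuronal differentiation and migration genes followed with 10 of 33 (odds ratio 8.38, exact adjusted p = 5.34e-05): Ncam1 (24 and 29 sites), Stmn2 (10 and 10), Map2 (18 and 17) and Satb2 (7 and 13), each with its highest region in the 3' UTR. The Pum1 knockout list, of 994 sites, had 5 in Ncam1, 1 in Stmn2, 1 in Map2 and 2 in Satb2, and also 4 in Btg1, 2 in Qk, 6 in Scn2a and 2 in Tcf4. RNA-binding protein genes had 7 of 36 (odds ratio 4.61, exact adjusted p = 0.0147), with Qk, Pum1, Pum2 and Zfp36l1. Epilepsy, ataxia and autism genes had 6 of 31 (odds ratio 4.58, exact adjusted p = 0.0232), with Scn2a, Stxbp1, Tcf4 and Arid1b. Without WT replicate 2 the odds ratio was 5.80 for known targets, 5.42 for neuronal differentiation and 2.81 for disease genes, all still called. With regions in exons alone the first 2 lists stayed past the threshold (exact adjusted p = 4.93e-04 each), and the RNA-binding and disease lists did not (odds ratios 3.72 and 4.09, exact adjusted p = 0.0721 each, with 315 targets in place of 374). Against random sets matched on 3' UTR length these last lists were not called either, at 3.39 and 3.47 times the random sets (permutation adjusted p = 0.0580 and 0.0827).

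Among Pum2 targets synapse genes led, with 15 of 39 (odds ratio 7.79, exact adjusted p = 2.43e-06): Dlg4 (2 and 6 sites), Nrxn3 (12 and 34), Camk2b (4 and 4) and Gria2 (19 and 8). Of these Dlg4, the scaffold of excitatory synapses, had its highest region in the 5' UTR and the others in introns. RNA-binding protein genes had 9 of 36 (odds ratio 4.11, exact adjusted p = 0.0115), with Lin28b, Cnot2, Elavl3 and Celf4, all intronic at their highest region. Ion channel genes had 7 of 28 (odds ratio 4.09, exact adjusted p = 0.0232), with Kcnq5, Scn2a, Kcnc1 and Kcnma1. In the Pum2 knockout lists Nrxn3 had 3 and 14 sites, Gria2 5 and 11, Elavl3 4 and 14 and Kcnma1 0 and 8. With exons alone, which left 159 of 563 targets, none of the 20 lists was called for Pum2. The synapse list then had 4 of 36 (odds ratio 3.69, exact adjusted p = 0.153), RNA-binding genes an odds ratio of 2.84 (exact adjusted p = 0.271) and ion channels 2.92 (exact adjusted p = 0.349). Without WT replicate 1 RNA-binding genes had an odds ratio of 2.40 (exact adjusted p = 0.0401). Without WT replicate 2 the synapse list had an odds ratio of 2.17 (exact adjusted p = 0.0655) and ion channels 1.62 (exact adjusted p = 0.416). With matching on 3' UTR length, RNA-binding genes and ion channels were not called, at 2.70 and 2.44 times the random sets (permutation adjusted p = 0.0688 and 0.208).

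The difference between the proteins was tested on genes that were targets of 1 of them. Neuronal differentiation genes were 7 for Pum1 alone and 2 for Pum2 alone (odds ratio 6.05, exact p = 0.0155, adjusted p = 0.0863), and known Pumilio targets were 5 and 1 (odds ratio 8.60, exact p = 0.0288, adjusted p = 0.0863). Synapse genes were 3 and 12 (odds ratio 0.417, exact adjusted p = 0.379). None of the 6 lists so tested differed between the proteins after adjustment.

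The remaining lists were not called for the protein named. Axon guidance genes had 5 of 35 for Pum1 (exact adjusted p = 0.0913), led by Plxna1, Nrp2, Slit2 and Robo2, and 7 for Pum2 (exact adjusted p = 0.0646), led by Epha3, Epha4, Plxna1 and Sema6d. Synapse genes were 6 of 39 for Pum1 (exact adjusted p = 0.0629), with Syt1, Vamp2, Gphn and Gabrg2. Ubiquitin ligase genes had 5 of 31 for Pum1 (exact adjusted p = 0.0731), among them Rnf44, Ube2g1, Ube2d2a and Cul3, and 0 for Pum2. Cell cycle genes had 3 of 23 for Pum1 (Btg1, Pcna and Cdkn1b, all in the 3' UTR, exact adjusted p = 0.225) and 0 for Pum2. Wnt, TGF-beta and BMP genes had 4 of 30 for Pum1, which were Gsk3b, Apc, Tcf4 and Tgfbr1, and 2 for Pum2, which were Axin1 and Gsk3b (exact adjusted p = 0.155 and 1). Neural stem cell genes had 2 of 20 for Pum1 (Msi2 and Id2) and 3 for Pum2 (Id2, Emx2 and Foxg1), with exact adjusted p = 0.465 and 0.347. MAPK and Ras genes had 1 of 25 for each protein, Map2k4 and Mapk10 (exact adjusted p = 1 each). Ion channels had 3 of 28 for Pum1 (Scn2a, Cacna2d1 and Kcna2, exact adjusted p = 0.320). For Pum2 known Pumilio targets had 5 of 27 (exact adjusted p = 0.142), neuronal differentiation genes 5 of 33 (exact adjusted p = 0.225) and disease genes 6 of 31 (exact adjusted p = 0.0895).

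**Figure D5:**
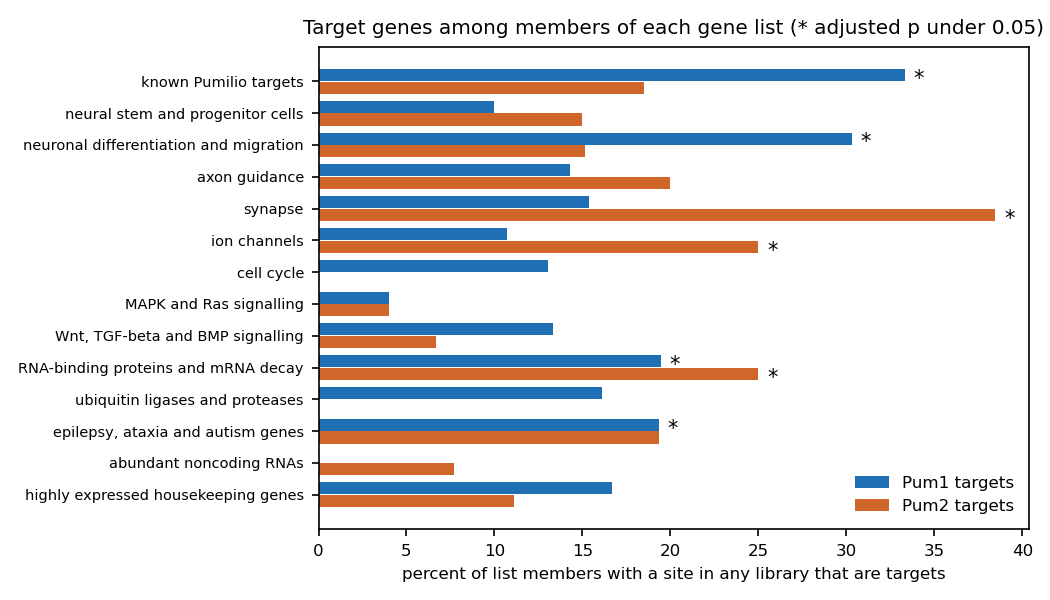
Share of list members with a site in any library that were targets (horizontal axis, percent), for Pum1 and Pum2 and the 14 lists with at least 10 such members. Stars mark adjusted p under 0.05; the highest bars are synapse genes for Pum2 (38.5%) and known Pumilio targets for Pum1 (33.3%).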

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

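The tests in this part were all chosen after the result was seen.

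The contrast of WT with knockout at the Pumilio element differed between the proteins. The odds ratio of the element was 23.2 for Pum2 (95% interval 8.63 to 62.2) and 1.38 for Pum1 (0.890 to 2.15), so that the ratio of both was 16.8 (5.69 to 49.4, exact test of equal odds ratios, p = 7.99e-10). This difference between the groups set it apart. It rested on Pum2 knockout replicate 2: without that list the ratio was 4.49 (exact p = 0.145), and within replicate 1 alone it was 4.57 (exact p = 0.143), so no difference was then detectable. Without WT replicate 1 or 2 it was 10.1 and 17.1. It counts sites, which are not independent, and for Pum1 it rests on 1 knockout library.

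The Pum1 knockout list of replicate 1 had 46.3% of its sites in 3' UTRs, in genes such as Pum2 and Atp2a2. Reads of WT Pum1 replicate 1 carried into this list were argued against as the source of all its sites. The element started 1 to 3 nt downstream at 0.333% of its exonic sites (95% interval 0.0404 to 1.20), below 2.35% (1.99 to 2.76) in the WT and knockout lists joined. Carry-over from WT Pum1 replicate 2, at 0.987% (0.823 to 1.18), stays open. Pum2 recovered by the Pum1 antibody was argued against as the source of all sites too, since WT Pum2 lists had 7.33% and 1.56% there (larger Fisher's exact p = 0.0145). A mix of either source with other sites would also lower the share, so it stays open. Norad, with its many Pumilio elements, had the most sites of any gene in the knockout list, 30. It had 38 in WT Pum1 and 26 in WT Pum2 replicate 1. That count goes with a mix of either kind and cannot tell them apart. Of the knockout sites, 7.44% and 4.83% lay exactly at sites of WT Pum2 replicates 1 and 2. RNA crosslinked without a Pumilio protein at the element stays open: its share in knockout windows over matched windows gave an odds ratio of 1.05 (0.564 to 1.96) in 1 draw of these windows and 0.870 to 3.59 over 100 draws, which reaches the 3.13 to 5.04 of WT replicate 1. The absence of Pum1 RNA from the list was not unusual, since 5 of 26 genes with like numbers and heights of WT sites (19.2%) had no knockout site either.

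The WT Pum1 and WT Pum2 lists of replicate 1 shared exact sites, with 14.1% of Pum1 sites found in the Pum2 list and 8.31% in the other Pum1 replicate, although within 50 nt the order turned to 26.1% and 39.0%. Repeated sequence counted at several places was argued against as the whole cause, since among exonic Pum2 replicate 1 sites 23.1% (21.5 to 24.9) were in that Pum1 list, compared with 9.94% (8.75 to 11.2) of replicate 2. A batch shared by every library of a number stays open: in replicate 2 the exonic share was 7.95% (6.87 to 9.13) within the number and 9.94% with the other, while over all sites it was 3.31% (3.0 to 3.64) and 2.57% (2.30 to 2.86). Carry-over between these 2 libraries, and binding of both proteins at the same bases in the same tissue, stay open and were not tested.

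Pum2 regions lay in introns of long genes such as Rbfox1, Nrxn3 and Pbx1. Gene length as the whole cause of the synapse call was argued against, since with matching on gene length the fold was 2.88 (15 genes against 5.22 in random sets, 95% range 1.98 to 9, permutation adjusted p = 0.00533), and 5.06 without matching. Gene length stays open for the ion channel list, where matching took the fold from 3.29 to 1.59 and so ended the call (7 genes against 4.42, 95% range 1 to 8, permutation adjusted p = 0.578). Background recovered without Pum2 stays open and may add to intronic regions: the share near a knockout site over the share near the other WT replicate was 0.482 and 0.167 in introns, and 0.264 and 0.0451 in 3' UTRs. Sequence in introns was not analysed here, so binding at intronic elements is untested.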

How the results depend on the processing

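Settings with repeats kept, sense sites, exons alone, gene length matching or equal heights removed were chosen after the data were seen, as were the setting without the empty list, the counting of repeats once and the settings of the ratio of odds ratios. Where no cause is given, the cause was not tested. Replicate overlap kept its side of the threshold under all 8 settings for each protein (5.68% to 28.5% for Pum1, 7.77% to 30.6% for Pum2), and so did the element in WT against matched windows under all 14 (odds ratios 1.80 to 8.49 and 2.31 to 15.1) and, by p not adjusted over tests, in Pum2 WT against knockout (5.18 to 50.9, highest exact p = 0.0422, without knockout replicate 2). Library by library the share of the element differed by 3.67 to 16.1 points (exact p = 0.0571 to 0.667). The 3' UTR difference stayed between 13.7 and 31.2 points without passing the threshold. The difference in sites passed it with repeats kept (1.53) and in sense sites within genes (1.62), and lay between 0.786 and 2.20 without a replicate. Comparison within replicate numbers (replicate block) gave 1.49, where an exact sign-flip test cannot pass the threshold. The labels give only numbers, and replicate differences of the groups barely correlated across the 7414 genes (r = 0.0210 to 0.196, over genes, which are not independent).

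Within 50 nt the knockout overlap was 3.64% (Pum1) and 17.8% (Pum2), and targets were 1107 and 1113. For Pum1 WT against knockout, UGUA gave 0.833, 50 nt 0.795 and 100 nt 0.749, in the opposite direction. By contrast, 3' UTR sites gave 1.66, and 1 WT replicate left out gave 1.07 to 2.13. WT regions set against knockout sites not selected for recurrence gave 3.97. The replicate block gave 2.13, which by construction uses replicate 1 alone. Enriched words were 2 for Pum1 with windows downstream; with 1 replicate left out they were 258 to 300 for Pum1 and 103 to 174 for Pum2, where every exonic site is counted. The ratio of the Pum2 to the Pum1 odds ratio was 4.49 without Pum2 knockout replicate 2 and 4.57 in replicate 1 alone, and no longer passed the threshold; without a WT replicate it was 10.1 to 17.1. The knockout filter on genes left 248 and 194 targets, and exons alone left 159 for Pum2. Leaving out a replicate, which by construction drops the need for overlap, gave 2457 to 4173 Pum1 and 3355 to 3614 Pum2 targets (374 and 563 at the lowest, without a knockout replicate). The target overlap without a replicate was 0.931 to 1.21, with 1.12 as the common odds ratio in the replicate block.

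Called lists for Pum1 were 2 with matching on 3' UTR length, 11 over all protein-coding genes, 9 to 12 without a replicate and 2 in exons. For Pum2 they were 1, 7, 2 to 6 and 0. Known Pumilio targets and neuronal differentiation kept their call under all 7 settings, and the other 5 calls lost it under 2 to 4. The knockout filter on whole genes was not among these settings, so whether any call holds under it was not tested. No setting matched genes on expression, so RNA abundance was not tested as a cause of the calls either. A site without extension gave no value, since it cannot hold the element. The small number of exonic windows limits what can be read from the Pum1 knockout (600) and Pum2 knockout replicate 1 (65).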

Other observations

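The count without groups of equal height was a test chosen after the data were seen, and the marker lists were not.

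Lists of cell type markers and abundant RNAs, fixed as controls, were not called for either protein. They had 2 to 18 members with a site, so a missing call says little. The Pum1 odds ratio was 12.6 for astrocyte markers, 18.9 for red blood cell genes and 3.79 for housekeeping genes. It was 0 for oligodendrocyte, microglia and vascular markers, abundant noncoding RNAs and mitochondrial transcripts. Astrocyte markers had 2 of 5 for Pum1 (exact adjusted p = 0.0834), the glutamate transporter gene Slc1a2 (4 and 25 sites) and Sparcl1 (3 and 7), and 1 for Pum2, Slc1a2 in an intron (exact adjusted p = 0.544). Oligodendrocyte markers had 0 of 6 and microglia markers 0 of 4 for both proteins. Vascular markers had 0 of 6 for Pum1 and 1 for Pum2 (Kdr, 1 and 1 sites, exact adjusted p = 0.604). Of 2 red blood cell genes with a site, Hba-a2 was a Pum1 target (exact adjusted p = 0.225), and none was a Pum2 target. Abundant noncoding RNAs had 0 of 13 for Pum1 and 1 for Pum2 (Rmst, exact adjusted p = 1). Mitochondrial protein-coding transcripts had 0 of 8 for both. Housekeeping genes had 3 of 18 for Pum1 (Actg1, Actb and Tubb2b, exact adjusted p = 0.155) and 2 for Pum2 (Tubb2a and Hsp90ab1, exact adjusted p = 0.952).

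Sites on the mitochondrial chromosome were listed in the knockouts, 8 in the Pum1 knockout and 19 in Pum2 knockout replicate 2, and 0 in the 4 WT lists; whether WT lists were filtered before deposit is not known, so this is not read as a difference in binding. Groups of at least 4 sites of exactly equal height, at 50 or more, made up 0.119% to 1.51% of each list. Without them there were 366 Pum1 and 545 Pum2 targets, and the target overlap was 3.42 times chance.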
